A study of Mus musculus with 14 samples.

How the data were processed

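RNA was measured in 14 libraries of mouse skin made with a QuantSeq forward kit, which sequences a short tag near the 3′ end of each polyadenylated transcript. The deposited table holds raw read counts per gene for 56953 genes in all 14 libraries, and whole-number values in every library column. Its gene length column, per the file headers, holds the other unit, summed exon length in bases, and was not used. The submitters' processing notes name STAR, featureCounts and DESeq2 and the builds GRCm38 and GRCm39, without roles or versions. Exon positions in the deposited counts table are those of GRCm39, so the positions given here are on that build. The strand setting and the handling of reads that map to several places are not given in the sources used here, so counts of near-identical paralogs and pseudogenes are uncertain. Genes of the Sprr2, Lce3, Stfa, Csta, Gsta and Skint families and ribosomal protein pseudogenes belong to this class.

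The labels give a genotype, a treatment and a replicate number, which makes 6 groups. Nothing in the labels says which animal a library came from, so every p-value measures spread between samples. Genes were kept with edgeR's filterByExpr, which left 16027 genes. Libraries were scaled by TMM, and 1 quasi-likelihood model with a mean for each of the 6 groups was fitted to all 14 libraries with edgeR 4.0.16 in R 4.3.3. The 9 comparisons were contrasts of this model. Of these, 5 compared pairs of groups, 1 compared the imiquimod responses of knockout and Cre-negative skin, and 3 compared Cre-negative with wild-type skin. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg correction over all genes tested, and the threshold was 0.05. Fold changes are on the log2 scale with the small prior count that edgeR's fit uses by default, and the value after ± is a standard error taken from the fold change and its F statistic. Log2 CPM for the principal components and the list tests used a prior count of 2. Expression levels are CPM with TMM scaling, given as mean ± SD with n as the number of libraries of the group. A group with 0 counts in all libraries was given a floor of 3 counts over the group, and a fold against it is stated as a lower bound. Floors and bounds cover counting error only, because reads without molecular identifiers are not independent molecules.

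Before the data were examined, 36 gene lists of pathways and cell types, the rule for named genes and most alternative settings were fixed. Of 867 list members, 864 were found in the table and 802 were tested, and 7 genes stood in more than 1 list. The 34 lists with at least 5 tested members were tested against all other genes with limma 3.58.1's camera at a preset correlation between genes of 0.01, with correction over 306 tests of lists and comparisons. At that preset 140 list tests passed the threshold. With the correlation estimated from the data 0 of the 306 passed, so each list is given with both p-values. The rotation test fry, which asks whether the genes of a list move 1 way on balance, passed 20, 16, 20, 14, 18 and 20 lists in the 6 main comparisons. In 0 lists past the threshold did the median, the mean and the test differ in sign, and they did in 33 of the other tests.

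Named genes were the 10 highest and the 10 lowest fold changes among genes past the threshold whose libraries did not overlap between the groups (a rule not used for differences between responses) and whose higher group averaged at least 5 CPM, without predicted genes that have no established symbol, up to 4 members of each list with the smallest p-values, and a fixed set of skin and inflammation genes. A gene named with a value and outside these is said to be chosen after its values were seen. Genes described as having risen or fallen kept that call when any 1 library was left out, except where a sentence says otherwise. In groups of 2 libraries this leaves 1, as does the use of female libraries only for Cre-negative DMSO skin. The lone library is then assumed to vary like those of the other groups, from which the spread is taken, so these settings are weak support.

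The procedure was tested on simulated counts with the library sizes and spread of these data and 200 changed genes in each comparison. It recovered at most 5% of the 2-fold changes in any comparison. Of the 4-fold changes it recovered 57.1% for knockout against Cre-negative skin with DMSO, 40.0% with imiquimod, 54.3%, 40.0% and 27.1% for imiquimod in Cre-negative, knockout and wild-type skin, and 11.4% for the difference between responses. Of the 16-fold changes it recovered 82.9% to 100% in those comparisons, with 1 to 9 false calls. Recovery may differ where more than 200 genes change.

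The alternatives were DESeq2 1.42.0 and limma voom with sample quality weights as other tools, median-of-ratios and upper-quartile scaling, library size alone, no filter and a stricter filter on low counts, a model of only the groups compared, a block for replicate number, muscle and adipocyte genes left out, and each library left out in turn. Added after seeing the data were a term for sex, female libraries only, ribosomal RNA genes left out, and the analysis without the 2 libraries with over 15% of counts from 18S ribosomal RNA. Library size alone, against TMM, shifted the median of all genes by -0.35 for knockout with DMSO, 0.39 for knockout with imiquimod, -0.57, 0.16 and -0.67 for imiquimod in Cre-negative, knockout and wild-type skin, and 0.74 for the difference between responses. Upper-quartile scaling shifted it by -0.12 for imiquimod in wild-type skin, 0.12 for Cre-negative against wild-type skin with imiquimod, and 0.12 for the difference between their responses. Changes are therefore relative to a scaling in which most genes are taken as stable. The reference annotation at hand was on GRCm38 and was not mixed with the deposited positions.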

Results

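The 14 libraries came from mouse skin of 3 genotypes. Wild-type C57BL/6J skin gave 2 libraries with DMSO and 2 with imiquimod. Mice with both copies of Nedd8 flanked by loxP sites and no Cre recombinase, called Cre-negative here, gave 3 with DMSO and 2 with imiquimod. Mice that also carried the K14-CreERT recombinase, which is meant to delete Nedd8 in keratinocytes after induction, and called knockout here, gave 3 with DMSO and 2 with imiquimod. NEDD8 is a small ubiquitin-like protein that is attached to cullins and switches on cullin-RING ubiquitin ligases. Imiquimod activates Toll-like receptor 7, and a cream with 5% of it applied daily from day 0 to day 7 gives mice a psoriasis-like skin inflammation. Knockout mice were induced on 5 days before the start. The labels give no induction for the other genotypes, so contrasts of knockout with Cre-negative skin may include the inducing treatment. The series title asks how NEDD8 and SUMO2 act in epithelial homeostasis, regeneration and inflammation, and the genotypes and treatments here address the part on NEDD8.

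The descriptions differ among themselves. The series design text speaks of wild-type mice given a NEDD8 inhibitor or DMSO on dorsal skin for 3 days, while the labels of the libraries give the genotypes and the imiquimod treatment used here. Cream was put on shaved backs or right ears, and no label says which site a library came from. The extraction text speaks of treated cells rather than tissue. No library had the cream without imiquimod, so the contrasts of imiquimod with DMSO include the cream base.

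Total counts per library, by replicate number, were 8294616 and 14748319 for wild-type DMSO, 31960197 and 13574424 for wild-type imiquimod, 15509178, 15437888 and 10839387 for Cre-negative DMSO, 7735269 and 20865337 for Cre-negative imiquimod, 5552954, 9814586 and 34362477 for knockout DMSO, and 13149797 and 10068739 for knockout imiquimod. Rn18s, the 18S ribosomal RNA, took 3.84% to 19.1% of counts, and was highest in Cre-negative imiquimod replicate 2 at 19.1% and knockout DMSO replicate 1 at 17.5%. The 10 most abundant genes of a library took 12.2% to 38.5%. S100a8 alone took 8.65% of counts in Cre-negative imiquimod replicate 2 and 8.21% in wild-type imiquimod replicate 1. Reads of Xist and 4 Y-linked genes marked all wild-type and all knockout DMSO libraries as female, all imiquimod libraries of Cre-negative and knockout skin as male, and the Cre-negative DMSO libraries as 2 male and 1 female. Sex therefore went with genotype among the DMSO libraries, apart from that 1 female, and with treatment among the knockout libraries.

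The first principal component held 39.6% of the variance and placed the 5 wild-type and Cre-negative DMSO libraries between -110 and -88.4, the 4 wild-type and Cre-negative imiquimod libraries between 22.3 and 39.4, and all 5 knockout libraries, treated or not, between 57.5 and 87.0. The second component, with 19.5%, set imiquimod-treated knockout skin at -121 and -89.3 apart from all other libraries.

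**Figure D1:**
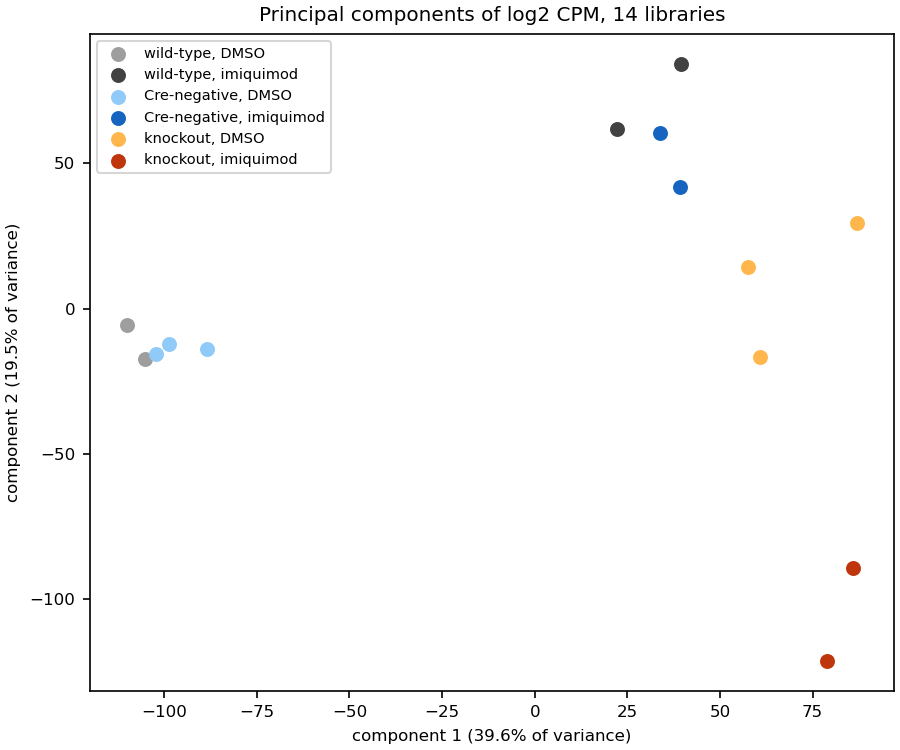
First and second principal components of log2 CPM for the 14 libraries, with the share of variance on each axis and colour by genotype and treatment. Knockout DMSO libraries lie between 57.5 and 87.0 on the first component, beyond the imiquimod-treated wild-type and Cre-negative libraries at 22.3 to 39.4.

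Nedd8 itself was measured to see whether the tag counts show the deletion. Nedd8 (ENSMUSG00000010376.16, minus strand of chromosome 14, 55899720 to 55909581 on GRCm39) averaged 226 ± 129 CPM (n = 3) in knockout DMSO skin and 313 ± 40.0 CPM (n = 3) in Cre-negative DMSO skin. With imiquimod it averaged 229 ± 111 CPM (n = 2) and 388 ± 104 CPM (n = 2), and in wild-type skin 237 ± 46.8 CPM with DMSO and 530 ± 218 CPM with imiquimod (n = 2 each). Over both treatments the exact two-sided permutation p was 0.117, where the smallest possible was 0.0167. With DMSO alone it was 0.4 (smallest possible 0.1) and with imiquimod alone 0.333 (smallest possible 0.333). The log2 fold change was -0.47 ± 0.40 with DMSO (adjusted p = 0.4) and -0.76 ± 0.50 with imiquimod (adjusted p = 0.33). With DMSO, library size alone gave -0.95 (adjusted p = 0.037) and voom -0.84 (adjusted p = 0.025), and the adjusted p ranged from 0.025 to 0.78 over all alternatives. Without the 2 libraries high in 18S ribosomal RNA the fold change was -0.98 with DMSO and -0.48 with imiquimod. Without knockout DMSO replicate 1, 2 or 3 it was -1.04, -0.27 or -0.24, and with imiquimod -1.36 or -0.38 without knockout replicate 1 or 2 and -0.42 without Cre-negative replicate 2. Library size alone gave -0.36 with imiquimod. Knockout DMSO replicate 1, at 375 CPM, lay above all 3 Cre-negative DMSO libraries (290 to 360 CPM). A lower level of Nedd8 was therefore not shown, and the tag near the 3′ end can lie outside the deleted part while skin also holds cells without the recombinase.

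Knockout against Cre-negative skin with DMSO asked how the 2 genotypes differ without imiquimod. Krt6a, a keratin of wounded and hyperproliferative epidermis, rose from 155 ± 26.8 to 17044 ± 2504 CPM (n = 3 each, log2 fold change 6.78 ± 0.44, adjusted p = 1.3e-06). Krt10, the main keratin of the layers above the basal layer, fell from 5660 ± 3446 to 30.9 ± 15.8 CPM (-7.53 ± 0.92, adjusted p = 8.8e-05). In total 2243 genes rose and 2509 fell of 16027 tested, and with library size alone 1183 rose and 3378 fell.

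Of the wound keratins and small proline-rich proteins, 22 of 25 rose (22 rose adjusted over the list alone), with a median of 5.55 (camera adjusted p = 3.5e-21, adjusted p = 0.12 with an estimated correlation). Krt16 (6.06 ± 0.58), Sprr2f (7.64 ± 0.66) and Sprr1b (4.76 ± 0.42) were among them. Of the IL-17 target and antimicrobial genes, 18 of 24 rose (19 rose and 1 fell adjusted over the list alone), with a median of 5.82 (camera adjusted p = 4.4e-13, adjusted p = 0.099 with an estimated correlation). Slpi (9.84 ± 0.53), a protease inhibitor of mucosal secretions, Defb4 (9.88 ± 0.74), a beta-defensin, and Saa3 (8.25 ± 0.83), an acute-phase protein, rose, and Il24, an IL-20 family cytokine, was at least 513-fold higher (30.9 ± 20.5 CPM, n = 3) with 0 counts in Cre-negative DMSO skin. S100a8, an alarmin subunit, rose by 7.05 ± 1.15 and S100a9 by 6.47 ± 0.99. Of the epidermal cytokines of barrier damage, 17 of 20 rose (18 rose adjusted over the list alone), with a median of 3.38, or 3.24 with genes at 0 counts at their bound (camera adjusted p = 8.7e-12, adjusted p = 0.065 with an estimated correlation). Nrg1 (4.85 ± 0.34) and Hbegf (4.50 ± 0.34), both ligands of the EGF receptor family, Il1b (4.68 ± 0.49) and the alarmin Il33 (3.35 ± 0.36) rose. Of the neutrophil markers, 10 of 20 rose and 1 fell (14 rose and 1 fell adjusted over the list alone), with a median of 2.57, or 2.28 with genes at 0 counts at their bound (camera adjusted p = 4.1e-06, adjusted p = 0.22 with an estimated correlation). Clec4d (5.35 ± 0.62), Trem1 (6.02 ± 0.72) and the granule collagenase Mmp8 (7.02 ± 0.95) were among them.

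Of the NRF2 targets, which carry the antioxidant response, 28 of 37 rose (30 rose and 2 fell adjusted over the list alone), with a median of 2.47 (camera adjusted p = 2.0e-16, adjusted p = 0.065 with an estimated correlation). Gsta4 (8.43 ± 0.46), a glutathione transferase, Gpx2 (8.59 ± 0.58), a glutathione peroxidase, Srxn1 (5.44 ± 0.35), sulfiredoxin, and Nqo1 (4.78 ± 0.49), a quinone reductase, rose. NRF2 is itself a substrate of a cullin 3 ligase. Of the proteasome subunits, 19 of 32 rose (22 rose adjusted over the list alone), with a median of 1.01 (camera adjusted p = 3.0e-07, adjusted p = 0.12 with an estimated correlation). Of the unfolded protein and integrated stress response genes, 16 of 28 rose and 2 fell (16 rose and 3 fell adjusted over the list alone), with a median of 0.95 (camera adjusted p = 3.1e-04, adjusted p = 0.099 with an estimated correlation). Of the heat shock and apoptosis genes, 10 of 22 rose (11 rose adjusted over the list alone), with a median of 0.72 (camera adjusted p = 0.0019, adjusted p = 0.14 with an estimated correlation). Mlkl (4.40 ± 0.58) and Ripk3 (3.06 ± 0.42), which carry out necroptosis, were among these. Of the cell cycle genes, 30 of 50 rose (38 rose adjusted over the list alone), with a median of 1.58 (camera adjusted p = 1.6e-12, adjusted p = 0.37 with an estimated correlation). Ccne1 (3.02 ± 0.39), cyclin E1 and a known substrate of cullin-RING ligases, Aurka (2.94 ± 0.40), a mitotic kinase, and Rrm2 (3.35 ± 0.46), a subunit of ribonucleotide reductase, rose. Of the p53 targets, 5 of 28 rose and 6 fell (5 rose and 7 fell adjusted over the list alone), with a median of -0.05, and the list did not pass (camera adjusted p = 0.88, adjusted p = 0.94 with an estimated correlation). Cdkn1a, the p21 inhibitor, stood at -0.04 ± 0.29 (adjusted p = 0.93).

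Of the suprabasal differentiation and cornified envelope genes, 5 of 45 rose and 21 fell (6 rose and 24 fell adjusted over the list alone), with a median of -1.33 (camera adjusted p = 2.6e-04, adjusted p = 0.58 with an estimated correlation). Krt77 (-11.19 ± 0.96), Flg2 (-6.34 ± 0.66) and Lce1j (-5.55 ± 0.63) fell. Of the sebaceous gland lipid genes, 1 of 27 rose and 15 fell (2 rose and 15 fell adjusted over the list alone), with a median of -2.61 (camera adjusted p = 3.3e-06, adjusted p = 0.14 with an estimated correlation). Far2 (-12.33 ± 0.79) makes fatty alcohols, Awat2 (-7.00 ± 0.58) makes wax esters and Mc5r (-6.71 ± 0.58) is the melanocortin receptor of sebocytes. Of the hair follicle stem cell and outer root sheath genes, 1 of 19 rose and 10 fell (2 rose and 10 fell adjusted over the list alone), with a median of -1.03 (camera adjusted p = 0.01, adjusted p = 0.26 with an estimated correlation). Krt79 (-4.31 ± 0.45) and Gata6 (-4.93 ± 0.59), both of the follicle's upper duct, fell. Of the basal keratinocyte and hemidesmosome genes, 9 of 18 rose and 2 fell (9 rose and 4 fell adjusted over the list alone), with a median of 1.11 (camera adjusted p = 0.031, adjusted p = 0.55 with an estimated correlation). Krt14 (2.65 ± 0.37) rose while Krt15 (-6.14 ± 0.40), a keratin of resting basal and stem cells, fell. This list did not pass with fry or without Cre-negative DMSO replicate 3 (median 1.15), knockout DMSO replicate 2 (0.87) or knockout DMSO replicate 3 (1.04).

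Of the dendritic and Langerhans cell markers, 14 of 18 fell (14 fell adjusted over the list alone), with a median of -3.17 (camera adjusted p = 1.7e-08, adjusted p = 0.12 with an estimated correlation). Ciita (-4.28 ± 0.38), the switch of MHC class II genes, H2-Eb1 (-3.68 ± 0.33) and H2-Aa (-3.78 ± 0.39) fell. Of the T cell and NK cell markers, 10 of 18 fell (10 fell adjusted over the list alone), with a median of -2.51 (camera adjusted p = 7.3e-04, adjusted p = 0.12 with an estimated correlation). Prf1 (-5.62 ± 0.65), perforin, and Cd3e (-5.09 ± 0.86), a chain of the T cell receptor complex, fell. Of the type I interferon response genes, 1 of 34 rose and 7 fell (1 rose and 6 fell adjusted over the list alone), with a median of -0.78 (camera adjusted p = 0.048, adjusted p = 0.61 with an estimated correlation). That call ended with fry, with 5 other scalings or gene sets and without Cre-negative DMSO replicate 3 or knockout DMSO replicate 2 or 3. Cxcl9 (-3.81 ± 0.68) and Irf9 (-1.41 ± 0.32) fell and Oasl1 (2.49 ± 0.42) rose, the calls of Irf9 and Oasl1 ending with a sex term and with female libraries only. Skint5 and Skint6, of a keratinocyte gene family, were at least 296-fold and 220-fold lower, with 0 counts in knockout DMSO skin. Some lists of deeper tissue fell, and the endothelial (median 0.45) and fibroblast (-0.65) lists did not pass. Of the skeletal muscle markers, 18 of 22 fell (20 fell adjusted over the list alone), with a median of -2.23 (camera adjusted p = 1.8e-07, adjusted p = 0.37 with an estimated correlation), and of the adipocyte markers, 7 of 16 fell (9 fell adjusted over the list alone), with a median of -1.36 (camera adjusted p = 0.0016, adjusted p = 0.4 with an estimated correlation). Of the HOX genes of trunk position, 8 of 22 fell (10 fell adjusted over the list alone), with a median of -0.79 (camera adjusted p = 0.0037, adjusted p = 0.11 with an estimated correlation). Casq1 (-3.98 ± 0.52), a calcium store protein of muscle, Car3 (-3.03 ± 0.38) and Hoxb2 (-1.56 ± 0.29) fell.

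The highest fold changes were in genes with few or no reads in Cre-negative DMSO skin. Spink12 was at least 770-fold higher, Dynap at least 445-fold higher, Sptssb, a subunit of the enzyme that starts sphingolipid synthesis, at least 290-fold higher, Krt76 at least 261-fold higher, Gcnt3, a mucin glycosyltransferase, at least 222-fold higher, and Ces1h at least 201-fold higher. Cxcl5 (10.28 ± 1.29), a neutrophil chemokine, Glyat (9.99 ± 0.91) and Fgf3 (9.90 ± 1.16) completed the highest. Among the lowest, AAdacl4fm3 was at least 705-fold lower, Serpinb6d at least 358-fold lower and Serpina3j at least 258-fold lower. Defb8 and S100a7l2 rested on Cre-negative DMSO replicate 1, with 65.4, 1.53 and 0.0729 CPM of Defb8 and 37.5, 8.97 and 0.364 CPM of S100a7l2 in replicates 1 to 3. Ddx3y is Y-linked and went with sex.

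Several settings moved the count of 4752 by more than 1.5 times. Voom called 7297 genes, a sex term left 1448, female libraries only, with a single Cre-negative library (n = 1), left 979, and leaving out Cre-negative DMSO replicate 1 or 2 gave 3148 and 3123. Of the 4752 genes, 4745 kept their direction with the sex term, the median absolute log2 fold change going from 1.80 to 1.73 and the median standard error from 0.42 to 0.59.

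**Figure D2:**
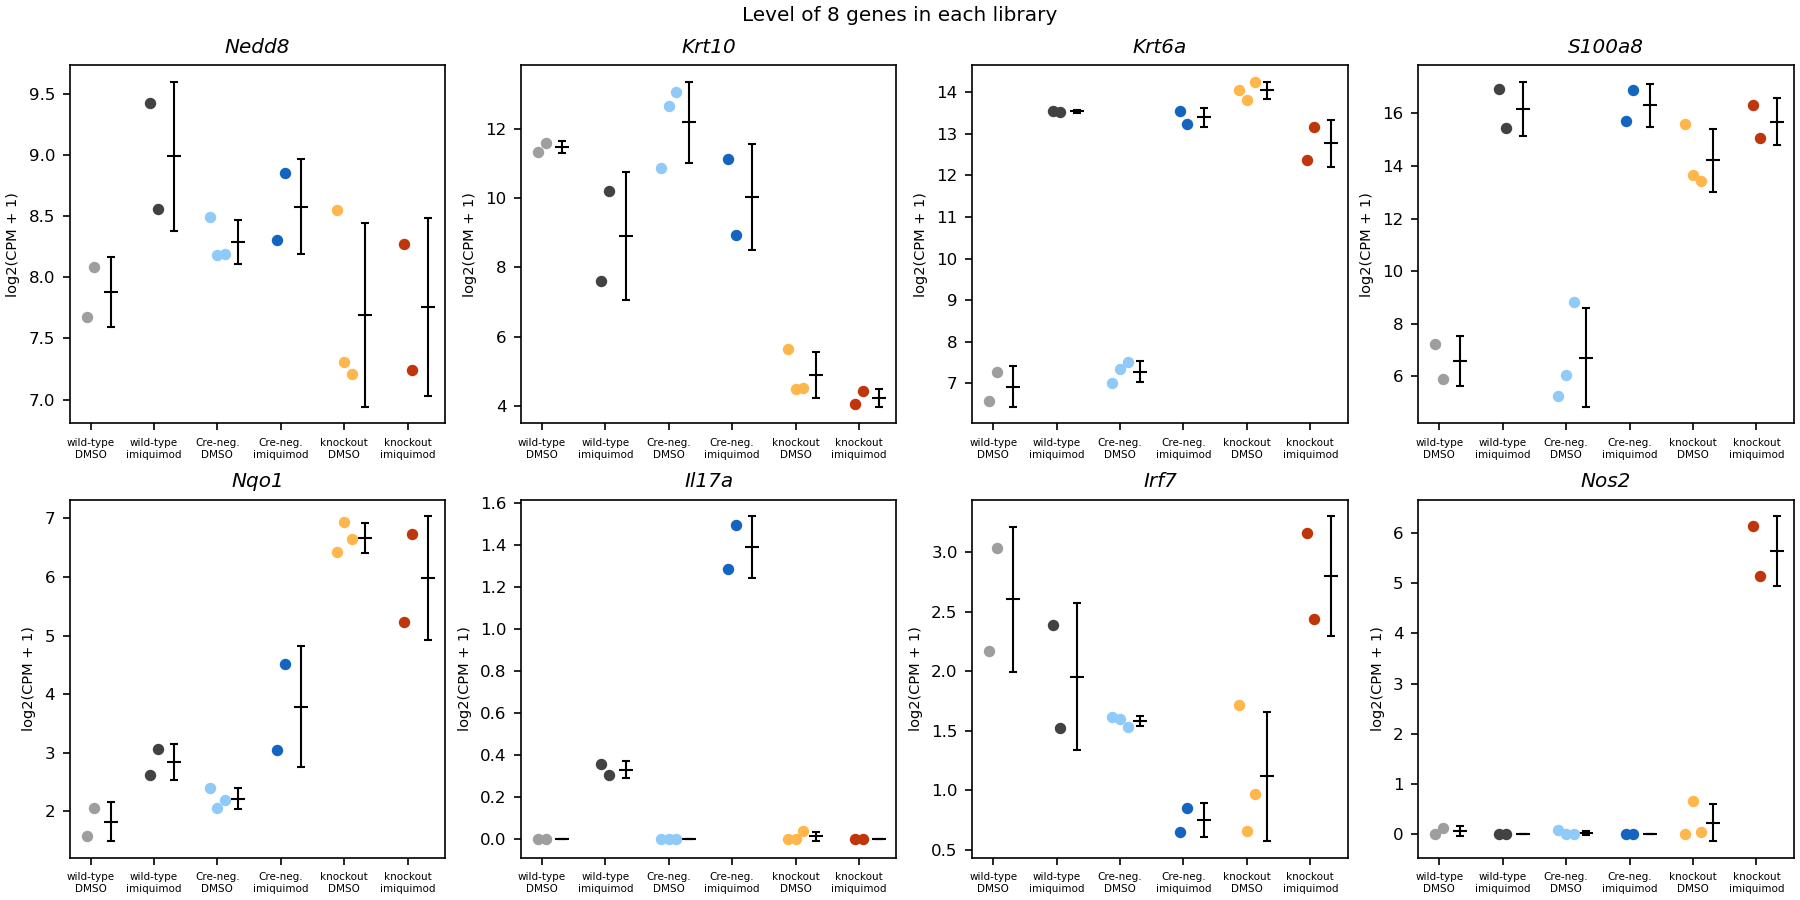
Level of 8 genes in each of the 14 libraries as log2 of CPM plus 1, with a point for each library and a bar for the group mean ± SD (n = 2 or 3). Krt10 averaged 5660 CPM in Cre-negative DMSO skin and 30.9 CPM in knockout DMSO skin, and Krt6a 155 and 17044 CPM.

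Imiquimod against DMSO in wild-type skin and in Cre-negative skin asked what the treatment does without the recombinase. S100a8 went from 105 ± 64.8 to 84372 ± 55461 CPM in wild-type skin (n = 2 each, 9.65 ± 1.57, adjusted p = 0.0014) and from 185 ± 232 (n = 3) to 87738 ± 47605 CPM (n = 2) in Cre-negative skin (8.89 ± 1.26, adjusted p = 5.1e-04). In wild-type skin 1537 genes rose and 1896 fell, and with library size alone 551 rose and 3608 fell. In Cre-negative skin 1307 rose and 1614 fell, and with library size alone 537 rose and 3141 fell.

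In wild-type skin, of the wound keratins and small proline-rich proteins 23 of 25 rose (23 rose and 1 fell adjusted over the list alone), with a median of 7.56, or 7.39 with genes at 0 counts at their bound (camera adjusted p = 2.3e-27, adjusted p = 0.099 with an estimated correlation). Krt16 (8.51 ± 0.79), Krt6a (6.59 ± 0.54) and Lce3b (12.12 ± 1.19), a late cornified envelope gene, were among them. Of the IL-17 target and antimicrobial genes, 19 of 24 rose (21 rose adjusted over the list alone), with a median of 5.65 (camera adjusted p = 2.2e-18, adjusted p = 0.065 with an estimated correlation). Il19 (11.42 ± 1.11) and Defb4 (6.50 ± 0.82) rose. Of the cytokine genes of the IL-23, IL-17 and IL-1 families, 9 of 17 rose and 1 fell (9 rose and 1 fell adjusted over the list alone), with a median of 2.39, or 2.22 with genes at 0 counts at their bound (camera adjusted p = 7.6e-06, adjusted p = 0.099 with an estimated correlation). Il23a (6.40 ± 0.79) and Il12b (8.76 ± 0.90) encode both chains of IL-23. Il17a was read at 0.258 ± 0.0345 CPM (n = 2) against 0 counts with DMSO, at least 2.60-fold higher (adjusted p = 0.042), and its call ended under 9 alternatives including every 1-library omission, the adjusted p ranging from 0.025 to 0.23. Of the neutrophil markers, 13 of 20 rose (13 rose adjusted over the list alone), with a median of 5.04, or 3.88 with genes at 0 counts at their bound (camera adjusted p = 9.1e-09, adjusted p = 0.14 with an estimated correlation). Of the HIF targets, 14 of 33 rose (16 rose adjusted over the list alone), with a median of 1.11 (camera adjusted p = 7.3e-06, adjusted p = 0.099 with an estimated correlation), with Slc16a3 (3.48 ± 0.43), a lactate transporter, and Egln3 (2.76 ± 0.36) among them. Of the melanocyte markers, 9 of 10 fell (9 fell adjusted over the list alone), with a median of -4.64, or -4.56 with genes at 0 counts at their bound (camera adjusted p = 6.7e-05, adjusted p = 0.33 with an estimated correlation). Of the adipocyte markers, 13 of 16 fell (13 fell adjusted over the list alone), with a median of -3.01 (camera adjusted p = 4.2e-08, adjusted p = 0.17 with an estimated correlation), of the skeletal muscle markers 13 of 22 fell (16 fell adjusted over the list alone), with a median of -2.19 (camera adjusted p = 1.0e-06, adjusted p = 0.39 with an estimated correlation), and of the HOX genes of trunk position 12 of 22 fell (14 fell adjusted over the list alone), with a median of -1.64 (camera adjusted p = 2.6e-05, adjusted p = 0.065 with an estimated correlation). Of the type I interferon response genes, 6 of 34 fell (4 fell adjusted over the list alone), with a median of -1.15 (camera adjusted p = 0.0029, adjusted p = 0.46 with an estimated correlation), Usp18 (-2.99 ± 0.59) among them. Without wild-type imiquimod replicate 1, wild-type DMSO replicate 2 or wild-type DMSO replicate 1 the count of 3433 was 1092, 1412 or 1608, and a model of only these groups gave 1863. Wild-type DMSO replicate 2 was high in melanocyte genes, at a mean log2 CPM of 4.81 against 2.09 in replicate 1, and in hair shaft genes, at 7.16 against 0.34.

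In Cre-negative skin, of the IL-17 target and antimicrobial genes 23 of 24 rose (23 rose adjusted over the list alone), with a median of 6.59, or 6.31 with genes at 0 counts at their bound (camera adjusted p = 8.4e-22, adjusted p = 0.065 with an estimated correlation), with Slpi (7.19 ± 0.49), Cxcl2 (6.32 ± 0.63) and Saa3 (9.06 ± 0.87) among them. Of the wound keratins and small proline-rich proteins, 22 of 25 rose and 1 fell (22 rose and 1 fell adjusted over the list alone), with a median of 6.22 (camera adjusted p = 2.6e-26, adjusted p = 0.11 with an estimated correlation). Krt6a (6.13 ± 0.44), Sprr2b (10.72 ± 1.08) and Lce3b (9.40 ± 0.80) rose. Il17a was read at 1.63 ± 0.270 CPM (n = 2) against 0 counts with DMSO, at least 27.0-fold higher (adjusted p = 0.0014), and Il23a (3.79 ± 0.55) rose. Of the cell cycle genes, 15 of 50 rose (19 rose adjusted over the list alone), with a median of 1.02 (camera adjusted p = 2.2e-08, adjusted p = 0.48 with an estimated correlation), Ccne1 (2.81 ± 0.41) among them, and that list did not pass with fry. Of the neutrophil markers, 12 of 20 rose (14 rose and 1 fell adjusted over the list alone), with a median of 4.24, or 3.50 with genes at 0 counts at their bound (camera adjusted p = 9.1e-09, adjusted p = 0.14 with an estimated correlation). Of the skeletal muscle markers, 22 of 22 fell (22 fell adjusted over the list alone), with a median of -3.38 (camera adjusted p = 1.1e-12, adjusted p = 0.22 with an estimated correlation), Casq1 (-4.46 ± 0.63) among them. Of the dendritic and Langerhans cell markers, 7 of 18 fell (8 fell adjusted over the list alone), with a median of -1.48 (camera adjusted p = 7.6e-06, adjusted p = 0.19 with an estimated correlation), with Mgl2 (-4.18 ± 0.60) and Cd74 (-2.54 ± 0.46) among them. Of the HOX genes of trunk position, 8 of 22 fell (11 fell adjusted over the list alone), with a median of -1.24 (camera adjusted p = 2.3e-04, adjusted p = 0.065 with an estimated correlation). Of the type I interferon response genes, 5 of 34 fell (5 fell adjusted over the list alone), with a median of -0.97, or -0.92 with genes at 0 counts at their bound (camera adjusted p = 2.3e-04, adjusted p = 0.36 with an estimated correlation). The median was -1.62 with library size alone, -1.55 without the 2 libraries high in 18S ribosomal RNA, and -0.62 or -1.61 without Cre-negative imiquimod replicate 1 or 2. Pyy, a gut hormone gene, was at least 864-fold lower with 0 counts under imiquimod. The count of 2921 was 1272 without Cre-negative imiquimod replicate 2, 1616 or 1644 without Cre-negative DMSO replicate 1 or 2, and 1762 without the 2 libraries high in 18S ribosomal RNA.

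The responses of wild-type and Cre-negative skin to imiquimod overlapped. Of the genes past the threshold, 724 rose in both (125 expected by chance), 944 fell in both (191 expected) and 2 went opposite ways (309 expected). Pearson's r was 0.70 and Spearman's rho 0.69 across 16027 genes, which are not independent replicates. Krt6a, Lce3b and Defb4 rose in both.

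Knockout skin without imiquimod was also set beside wild-type skin with imiquimod, which share no libraries. Of the genes past the threshold, 977 rose in both (215 expected), 1108 fell in both (297 expected) and 31 went opposite ways (506 expected), and r was 0.61 across genes. The 1537 genes that rose with imiquimod in wild-type skin had a median of 1.22 in knockout DMSO skin (camera p = 3.5e-50, p = 0.0017 with an estimated correlation), and the 1896 that fell had a median of -1.50 (camera p = 1.3e-38, p = 0.00094 with an estimated correlation). The muscle, adipocyte and trunk HOX lists fell in both contrasts, so a site or tissue shift stays open.

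**Figure D3:**
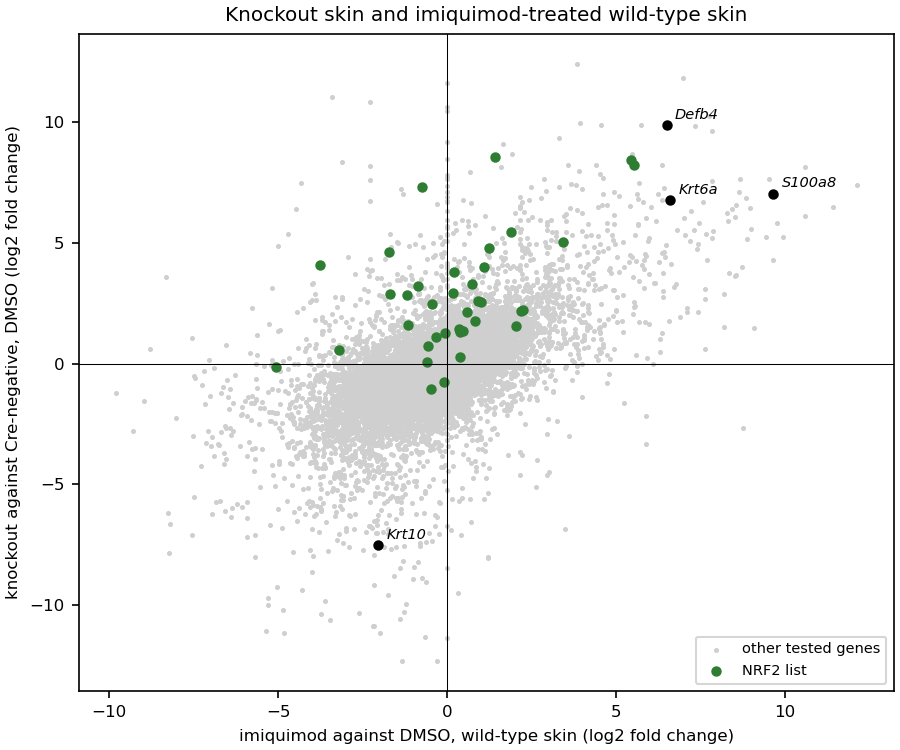
Log2 fold change of 16027 genes in knockout against Cre-negative skin with DMSO, on the vertical axis, against imiquimod in wild-type skin, on the horizontal axis, with a point for each gene and the 37 NRF2 targets in green. Pearson's r across genes was 0.61, and 31 genes past both thresholds went opposite ways.

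Imiquimod against DMSO in knockout skin asked what the treatment does in that genotype. Il1b rose from 67.1 ± 37.2 (n = 3) to 2477 ± 357 CPM (n = 2, 5.20 ± 0.51, adjusted p = 8.8e-05). Krt6a stood at 17044 ± 2504 and 7257 ± 2770 CPM (-1.23 ± 0.40, adjusted p = 0.064). In total 1372 genes rose and 404 fell, and with library size alone 1429 rose and 186 fell. Of the neutrophil markers, 17 of 20 rose (17 rose adjusted over the list alone), with a median of 5.63 (camera adjusted p = 1.8e-19, adjusted p = 0.065 with an estimated correlation). Clec4e (6.63 ± 0.45), Stfa2l1 (6.86 ± 0.54) and Trem1 (5.70 ± 0.54) were among them. Ngp and Ltf, neutrophil granule proteins, rose by 12.13 and 9.62. Of the monocyte and macrophage markers, 16 of 22 rose (19 rose adjusted over the list alone), with a median of 2.28 (camera adjusted p = 9.0e-11, adjusted p = 0.18 with an estimated correlation). Cd14 (5.23 ± 0.47), Ly6c2 (5.74 ± 0.66) and Nos2 (8.16 ± 0.90), the inducible nitric oxide synthase, were among them. Of the NF-kB targets, 14 of 20 rose (16 rose adjusted over the list alone), with a median of 1.81 (camera adjusted p = 3.6e-09, adjusted p = 0.12 with an estimated correlation), with Traf1 (5.40 ± 0.72) and Tnfaip3 (3.46 ± 0.52) among them. Of the type I interferon response genes, 9 of 34 rose (14 rose adjusted over the list alone), with a median of 1.33 (camera adjusted p = 5.3e-07, adjusted p = 0.21 with an estimated correlation). Trim30a (2.54 ± 0.36) and Cxcl9 (4.09 ± 0.72) rose. Ifitm6 (8.18 ± 0.66), outside the lists, was among the 10 highest fold changes. Of the suprabasal differentiation and cornified envelope genes, 11 of 45 fell (18 fell adjusted over the list alone), with a median of -1.33 (camera adjusted p = 7.1e-11, adjusted p = 0.33 with an estimated correlation). Of the wound keratins and small proline-rich proteins, 1 of 25 fell (1 fell adjusted over the list alone), with a median of -0.84 (camera adjusted p = 2.7e-04, adjusted p = 0.52 with an estimated correlation). That list did not pass with fry, with a sex term (median 0.05) or without knockout imiquimod replicate 1 (-0.28). Of the cell cycle genes, 5 of 50 fell (5 fell adjusted over the list alone), with a median of -0.87 (camera adjusted p = 3.1e-08, adjusted p = 0.49 with an estimated correlation), and that list did not pass with fry. Of the IL-17 target and antimicrobial genes, 9 of 24 rose (11 rose and 2 fell adjusted over the list alone), with a median of 1.56 (camera adjusted p = 0.0087, adjusted p = 0.47 with an estimated correlation), with Cxcl2 (5.32 ± 0.56) and Csf3 (4.84 ± 0.59) among them. The median was 3.35 with a sex term and 0.99 without knockout imiquimod replicate 1, and the list did not pass without knockout imiquimod replicate 2 (1.87). Of the cytokine genes of the IL-23, IL-17 and IL-1 families, 7 of 17 rose and 1 fell (9 rose and 3 fell adjusted over the list alone), with a median of 1.56 (camera adjusted p = 0.002, adjusted p = 0.17 with an estimated correlation), with Tnf (5.32 ± 0.54) and Il1rl1 (4.98 ± 0.59) among them, and the median was 2.46 with a sex term. Of the epidermal cytokines of barrier damage, 9 of 20 rose and 2 fell (12 rose and 3 fell adjusted over the list alone), with a median of 1.37 (camera adjusted p = 7.9e-04, adjusted p = 0.18 with an estimated correlation), with Mmp10 (4.80 ± 0.62) and Plaur (4.13 ± 0.56) among them. Of the hair follicle stem cell and outer root sheath genes, 5 of 19 fell (1 rose and 7 fell adjusted over the list alone), with a median of -1.01 (camera adjusted p = 0.0055, adjusted p = 0.22 with an estimated correlation), and the median was -0.55 in a model of only these groups and -1.62 with a sex term. Krt15 (-3.63 ± 0.44) fell. Of the endothelial markers, 2 of 18 rose (5 rose adjusted over the list alone), with a median of 1.10 (camera adjusted p = 0.0012, adjusted p = 0.33 with an estimated correlation), and the median was 0.63 without knockout imiquimod replicate 1. Of the adipocyte markers, 2 of 16 fell (5 fell adjusted over the list alone), with a median of -0.46 (camera adjusted p = 0.01, adjusted p = 0.5 with an estimated correlation). That list did not pass with fry or without knockout imiquimod replicate 2 (-0.28), and the median was -0.85 with a sex term and -1.08 without knockout imiquimod replicate 1. Neither the HOX nor the skeletal muscle list passed the test (adjusted p = 0.80 and 0.43).

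Sex went with treatment in this contrast, and the Y-linked Ddx3y, Eif2s3y and Kdm5d were among the 10 highest. The count of 1776 was 210 with a sex term, 339 without knockout imiquimod replicate 1, 832 without knockout DMSO replicate 3 and 1028 in a model of only these groups. Of the 1776 genes, 1759 kept their direction with the sex term, the median absolute log2 fold change going from 2.32 to 2.28 and the median standard error from 0.50 to 0.81, which ended the calls of Clec4e, Stfa2l1, Ngp, Ltf, Nos2, Csf3 and Mmp10.

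Knockout against Cre-negative skin with imiquimod asked how the treated genotypes differ, and all 4 libraries were male. Nos2 was at least 378-fold higher, at 51.9 ± 24.8 CPM (n = 2) against 0 counts in Cre-negative imiquimod skin (n = 2, adjusted p = 4.7e-04). Krt10 fell from 1363 ± 1233 to 17.9 ± 3.48 CPM (n = 2 each, -6.25 ± 1.07, adjusted p = 0.002). In total 1852 genes rose and 1014 fell, and with library size alone 2443 rose and 496 fell.

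Of the neutrophil markers, 15 of 20 rose and 2 fell (17 rose and 2 fell adjusted over the list alone), with a median of 5.37 (camera adjusted p = 6.3e-11, adjusted p = 0.12 with an estimated correlation). Clec4e (5.59 ± 0.50), Stfa2l1 (6.00 ± 0.61) and Trem1 (5.15 ± 0.62) rose, as did Csf3 (5.87 ± 0.74), the granulocyte growth factor, Cxcl2 (4.79 ± 0.65), a neutrophil chemokine, and Il1b (4.69 ± 0.59). Camp, the antimicrobial cathelicidin, was at least 95.8-fold higher. Of the monocyte and macrophage markers, 11 of 22 rose and 1 fell (11 rose and 1 fell adjusted over the list alone), with a median of 1.64 (camera adjusted p = 3.7e-04, adjusted p = 0.46 with an estimated correlation). Cd14 (5.78 ± 0.57) and Ly6c2 (4.15 ± 0.70) rose while Cx3cr1 (-2.27 ± 0.36) fell. Of the type I interferon response genes, 13 of 34 rose (16 rose adjusted over the list alone), with a median of 1.71 (camera adjusted p = 3.1e-07, adjusted p = 0.2 with an estimated correlation). Oas2 (6.15 ± 0.90) and Oasl1 (4.07 ± 0.56) were among them. Of the NF-kB targets, 9 of 20 rose (10 rose adjusted over the list alone), with a median of 1.69 (camera adjusted p = 9.1e-05, adjusted p = 0.29 with an estimated correlation), Tnfaip3 (3.06 ± 0.59) among them. Of the endothelial markers, 11 of 18 rose (13 rose adjusted over the list alone), with a median of 2.37 (camera adjusted p = 3.1e-06, adjusted p = 0.17 with an estimated correlation), with Kdr (2.60 ± 0.48) and Eng (3.15 ± 0.59) among them. Of the dendritic and Langerhans cell markers, 6 of 18 fell (3 rose and 7 fell adjusted over the list alone), with a median of -1.55, or -1.02 with genes at 0 counts at their bound (camera adjusted p = 0.0097, adjusted p = 0.43 with an estimated correlation), with H2-Eb1 (-2.28 ± 0.38) and Ciita (-2.44 ± 0.44) among them. That list did not pass without the 2 libraries high in 18S ribosomal RNA (-0.48), Cre-negative imiquimod replicate 2 (-0.42) or knockout imiquimod replicate 2 (-1.51), and the median was -0.96 both with a stricter filter on low counts and in a model of only these groups. Of the melanocyte markers, 7 of 10 rose (9 rose adjusted over the list alone), with a median of 3.69, or 2.74 with genes at 0 counts at their bound (camera adjusted p = 8.0e-04, adjusted p = 0.39 with an estimated correlation). Of the NRF2 targets, 22 of 37 rose and 1 fell (24 rose and 2 fell adjusted over the list alone), with a median of 1.65 (camera adjusted p = 4.2e-08, adjusted p = 0.13 with an estimated correlation). Srxn1 (3.55 ± 0.39), Gpx2 (5.45 ± 0.61) and Gclc (5.20 ± 0.66), a subunit of the enzyme that starts glutathione synthesis, rose. Of the epidermal cytokines of barrier damage, 10 of 20 rose and 2 fell (12 rose and 3 fell adjusted over the list alone), with a median of 2.26 (camera adjusted p = 7.5e-04, adjusted p = 0.18 with an estimated correlation). The matrix proteases Mmp13 (5.86 ± 0.71) and Mmp10 (6.63 ± 0.82) rose and Il33 (-2.92 ± 0.43) fell.

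Of the suprabasal differentiation and cornified envelope genes, 32 of 45 fell (36 fell adjusted over the list alone), with a median of -2.83 (camera adjusted p = 4.2e-19, adjusted p = 0.18 with an estimated correlation). Casp14 (-4.42 ± 0.50), a protease of cornification, Tgm5 (-4.22 ± 0.50), Klk5 (-3.50 ± 0.35) and Dsg1a (-3.61 ± 0.49), a desmosomal cadherin, fell. Of the sebaceous gland lipid genes, 1 of 27 rose and 9 fell (1 rose and 12 fell adjusted over the list alone), with a median of -1.09 (camera adjusted p = 1.9e-07, adjusted p = 0.12 with an estimated correlation). Elovl3 (-10.33 ± 1.15), Far2 (-8.43 ± 0.77) and Awat1 (-7.93 ± 1.06) fell. Of the wound keratins and small proline-rich proteins, 1 of 25 rose and 10 fell (2 rose and 11 fell adjusted over the list alone), with a median of -1.22 (camera adjusted p = 3.7e-06, adjusted p = 0.4 with an estimated correlation), with Krt17 (-2.28 ± 0.40) and Sprr2b (-4.79 ± 0.95) among them. The IL-17 target and antimicrobial list did not pass (median 0.60, adjusted p = 0.57), with 8 of its 24 genes past the threshold upward and 4 downward. Il17a was at least 13.2-fold lower (adjusted p = 0.0052), with 1.63 ± 0.270 CPM in Cre-negative skin (n = 2) against 0 counts in both knockout libraries, and without knockout imiquimod replicate 1 its adjusted p was 0.058, the alternatives ranging from 0.0010 to 0.058. The 2866 genes became 796 without knockout imiquimod replicate 1, 1497 or 1477 without Cre-negative imiquimod replicate 1 or 2, and 1790 with voom.

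The genotype effects with and without imiquimod were compared across genes. Of the genes past the threshold in each, 414 were higher in knockout skin in both settings (259 expected), 330 were lower in both (159 expected) and 410 went opposite ways (432 expected). Pearson's r was 0.23 and Spearman's rho -0.01 across genes. Far2, Krt79 and Krt15 fell and Gpx2 and Srxn1 rose in both, while Il33 (3.35 and -2.92) went opposite ways. The response itself, imiquimod minus DMSO, differed between knockout and Cre-negative skin in 3785 genes, 2242 upward and 1543 downward. With library size alone these were 3650 and 511, with a sex term 1469 genes passed, and without knockout imiquimod replicate 1 there were 1174. Over the 3433 genes past the threshold in wild-type skin, the slope of the knockout response on the Cre-negative response was -0.0063 (SD 0.030 over left-out libraries), where 1 would be an equal response. Its sign was not stable, being positive under 12 of 27 alternatives, highest with a sex term (0.110), without wild-type imiquimod replicate 1 (0.0609) and without knockout imiquimod replicate 1 (0.0604).

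**Figure D4:**
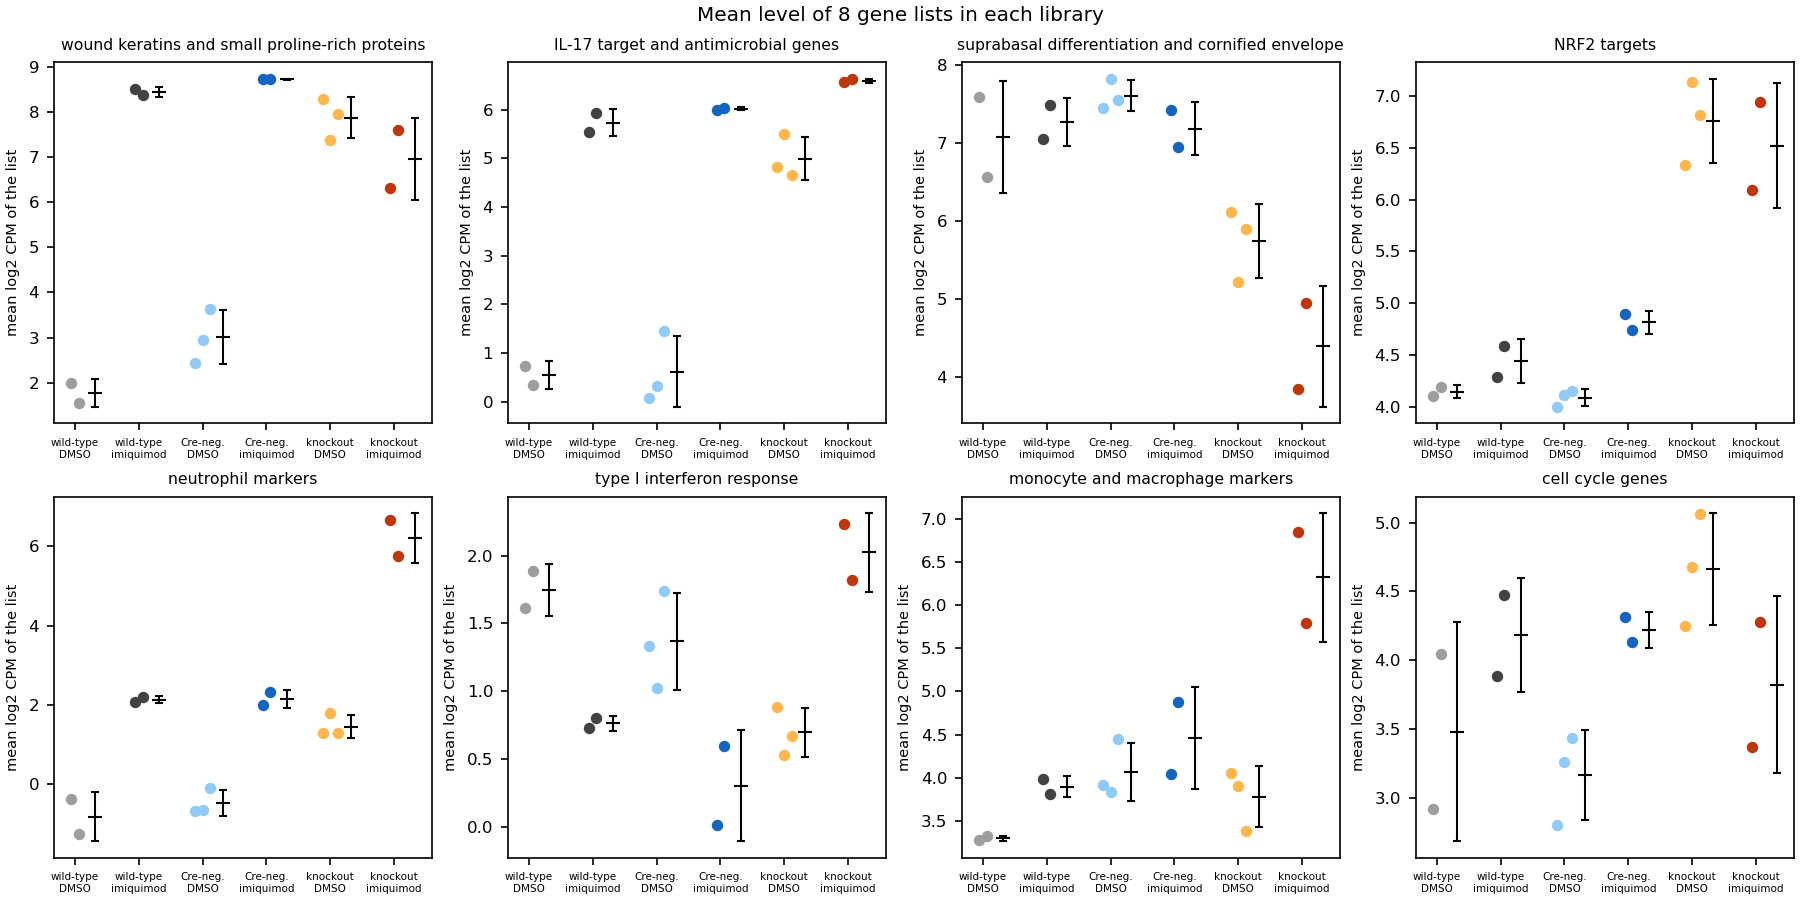
Mean log2 CPM of the genes of 8 lists in each of the 14 libraries, with a point for each library and a bar for the group mean ± SD (n = 2 or 3). Neutrophil and macrophage lists were highest in imiquimod-treated knockout skin, and the NRF2 list was higher in all 5 knockout libraries than in the other 9.

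Cre-negative against wild-type skin asked whether the floxed strain differs from wild-type skin. With DMSO 0 genes passed edgeR's test (1120 at an unadjusted p under 0.05, 801 expected), against 144 with DESeq2 and 195 with voom, and 188 without wild-type DMSO replicate 1. With imiquimod 0 genes passed (2747 unadjusted), against 542 with DESeq2 and 0 with voom, and 557 without wild-type imiquimod replicate 2. For the difference between their responses 0 passed (1466 unadjusted), against 53 with DESeq2 and 0 with voom. Of the 35 hair shaft and inner root sheath genes 0 passed with DMSO (32 fell adjusted over the list alone), with a median of -6.51 (camera adjusted p = 2.9e-18, adjusted p = 0.31 with an estimated correlation). Of the 10 melanocyte markers 0 passed (7 fell adjusted over the list alone), with a median of -4.17 (camera adjusted p = 1.8e-11, adjusted p = 0.12 with an estimated correlation). Both lists were high in wild-type DMSO replicate 2, and without it the medians were 0.64, which did not pass, and -1.62, which did. Camera passed 14 lists with DMSO and 9 with imiquimod. With DMSO fry also passed the melanocyte list and 5 others. Of the 25 wound keratins and small proline-rich proteins, 0 passed the threshold (8 rose adjusted over the list alone), with a median of 1.75, or 1.65 with genes at 0 counts at their bound (camera adjusted p = 2.9e-14, adjusted p = 0.18 with an estimated correlation), and the median was 0.98 without Cre-negative DMSO replicate 3. Of the 18 dendritic and Langerhans cell markers, 0 passed the threshold (1 rose adjusted over the list alone), with a median of 0.91 (camera adjusted p = 1.0e-07, adjusted p = 0.14 with an estimated correlation). Of the 33 HIF targets, 0 passed the threshold (2 rose adjusted over the list alone), with a median of 0.55 (camera adjusted p = 1.2e-08, adjusted p = 0.065 with an estimated correlation). Of the 16 adipocyte markers, 0 passed the threshold (11 fell adjusted over the list alone), with a median of -1.44 (camera adjusted p = 3.0e-15, adjusted p = 0.099 with an estimated correlation). Of the 19 hair follicle stem cell and outer root sheath genes, 0 passed the threshold (1 rose and 7 fell adjusted over the list alone), with a median of -0.78 (camera adjusted p = 5.9e-05, adjusted p = 0.12 with an estimated correlation), and the median was -0.38 without wild-type DMSO replicate 2. With imiquimod fry also passed 1 of the 9, the T cell and NK cell markers, of which 0 of 18 passed the threshold (0 passed adjusted over the list alone), with a median of 0.80 (camera adjusted p = 0.01, adjusted p = 0.2 with an estimated correlation), and this call ended without a filter on low counts and without wild-type imiquimod replicate 2 or Cre-negative imiquimod replicate 1. Sex and strain cannot be told apart in the imiquimod contrast, where all wild-type libraries were female and all Cre-negative libraries male.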

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

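Of the tests weighed here, only that of the epidermis share was chosen after its result was seen, and the sex term and the female libraries used beside them were also added after seeing the data. The gene and list differences given first were picked out because the test of the difference itself passed the threshold, between the imiquimod responses of knockout and Cre-negative skin or of Cre-negative and wild-type skin. That difference passed in 3785 genes for knockout skin and in 0 genes for Cre-negative against wild-type skin. The 3 patterns weighed after them come from comparisons of 2 groups.

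With the fitted difference of log2 responses, knockout minus Cre-negative, the 10 highest were Pyy 13.16, Scrg1 13.09, Fam169b 12.59, Ddx3y 11.48, Ngp 10.62, Dab1 10.60, Ifitm6 9.88, Frzb 8.96, Ltf 8.89 and Clca1 8.88. Pyy, Scrg1, Fam169b, Dab1 and Frzb had 0 counts in Cre-negative imiquimod skin, so these fitted values depend on the prior count and are no bounds. Mean CPM in Cre-negative DMSO, knockout DMSO and knockout imiquimod skin was 119, 0.0887 and 0.0886 for Pyy, 0.331, 0.0647 and 11.4 for Scrg1, 0.927, 0.125 and 7.53 for Fam169b, 12.2, 0.0188 and 0.0443 for Dab1, and 6.17, 0.732 and 0.418 for Frzb. Ngp stood at 666 CPM in knockout imiquimod skin and at most 0.464 CPM in the other groups, and Ddx3y is Y-linked.

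The 10 lowest were Sprr2b -12.44, Fam3d -11.75, Spink12 -11.21, Defb3 -10.88, Lce3b -10.53, Klk14 -10.42, Defb4 -10.06, Cdhr1 -9.73, Csta3 -9.29 and Sprr2d -9.27. Fam3d and Spink12 had 0 counts in Cre-negative DMSO skin, and with imiquimod, knockout DMSO and knockout imiquimod Fam3d stood at 6.45, 1.37 and 0.259 CPM and Spink12 at 7.91, 46.3 and 18.5 CPM. Among the fixed genes the difference was 3.94 for Irf7, -7.36 for Krt6a, -7.43 for Krt16, -4.49 for Krt17, -3.43 for Krt14, -7.65 for S100a8, -7.66 for S100a9, -2.52 for Nqo1, -2.29 for Il23a and -9.36 for Il17a, whose counts were 0 in Cre-negative DMSO and knockout imiquimod skin.

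The gene lists whose response was lower in knockout skin had medians as follows, wound keratins and small proline-rich proteins -7.26 (1 of 25 higher and 22 lower, 1 and 23 adjusted over the list alone, camera adjusted p = 1.5e-22, adjusted p = 0.12 with an estimated correlation), IL-17 target and antimicrobial genes -4.13 (0 of 24 higher and 13 lower, 0 and 14 adjusted over the list alone, camera adjusted p = 1.7e-08, adjusted p = 0.14 with an estimated correlation), cell cycle genes -1.97 (0 of 50 higher and 27 lower, 0 and 32 adjusted over the list alone, camera adjusted p = 1.7e-12, adjusted p = 0.37 with an estimated correlation) and proteasome subunits -1.49 (0 of 32 higher and 11 lower, 0 and 18 adjusted over the list alone, camera adjusted p = 3.3e-08, adjusted p = 0.12 with an estimated correlation). Lower as well were suprabasal differentiation and cornified envelope -1.27 (2 of 45 higher and 14 lower, 2 and 18 adjusted over the list alone, camera adjusted p = 3.1e-04, adjusted p = 0.58 with an estimated correlation), unfolded protein and integrated stress response -1.08 (2 of 28 higher and 8 lower, 2 and 8 adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.12 with an estimated correlation), heat shock and apoptosis genes -0.90 (1 of 22 higher and 7 lower, 2 and 7 adjusted over the list alone, camera adjusted p = 0.044, adjusted p = 0.31 with an estimated correlation), epidermal innate cytokines of barrier damage -0.86 (0 of 20 higher and 7 lower, 0 and 8 adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.36 with an estimated correlation), NRF2 targets -0.77 (2 of 37 higher and 12 lower, 3 and 12 adjusted over the list alone, camera adjusted p = 0.0013, adjusted p = 0.35 with an estimated correlation) and neddylation machinery and cullin-RING ligase core -0.56 (3 of 42 higher and 6 lower, 3 and 4 adjusted over the list alone, camera adjusted p = 0.0066, adjusted p = 0.17 with an estimated correlation).

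Higher in knockout skin were skeletal muscle markers 3.21 (18 of 22 higher and 0 lower, 22 and 0 adjusted over the list alone, camera adjusted p = 9.2e-07, adjusted p = 0.39 with an estimated correlation), type I interferon response 2.37 (17 of 34 higher and 0 lower, 22 and 0 adjusted over the list alone, camera adjusted p = 1.5e-07, adjusted p = 0.19 with an estimated correlation), monocyte and macrophage markers 2.29 (10 of 22 higher and 1 lower, 16 and 1 adjusted over the list alone, camera adjusted p = 6.0e-04, adjusted p = 0.47 with an estimated correlation), endothelial markers 1.98 (6 of 18 higher and 0 lower, 7 and 0 adjusted over the list alone, camera adjusted p = 0.0074, adjusted p = 0.4 with an estimated correlation) and dendritic and Langerhans cell markers 1.85 (9 of 18 higher and 0 lower, 10 and 0 adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.35 with an estimated correlation). Further lists with a higher response were NF-kB targets 1.54 (9 of 20 higher and 0 lower, 11 and 2 adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.56 with an estimated correlation), trunk position HOX genes 1.25 (6 of 22 higher and 0 lower, 6 and 0 adjusted over the list alone, camera adjusted p = 0.031, adjusted p = 0.17 with an estimated correlation), fibroblast and extracellular matrix genes 1.06 (9 of 25 higher and 1 lower, 10 and 1 adjusted over the list alone, camera adjusted p = 0.0083, adjusted p = 0.58 with an estimated correlation) and neutrophil markers 0.23 (4 of 20 higher and 2 lower, 4 and 2 adjusted over the list alone, camera adjusted p = 0.0084, adjusted p = 0.48 with an estimated correlation). Of these calls in either direction, fry ended those of the suprabasal and heat shock lists, library size alone those of the NF-kB, neddylation, heat shock and neutrophil lists, and the sex term those of the heat shock, barrier damage and HOX lists. A stricter filter ended that of the heat shock list, and 1 or more omissions those of the NF-kB, heat shock, barrier damage, fibroblast and HOX lists.

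Between Cre-negative and wild-type responses, where 0 genes passed edgeR's test, 8 lists passed camera. Their medians, Cre-negative minus wild-type, were melanocyte markers 3.24 (0 of 10 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 1.7e-04, adjusted p = 0.35 with an estimated correlation), adipocyte markers 0.45 (0 of 16 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 0.031, adjusted p = 0.57 with an estimated correlation), wound keratins and small proline-rich proteins -1.57 (0 of 25 higher and 0 lower, 0 and 2 adjusted over the list alone, camera adjusted p = 9.7e-05, adjusted p = 0.49 with an estimated correlation) and skeletal muscle markers -1.23 (0 of 22 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 3.0e-04, adjusted p = 0.53 with an estimated correlation). The rest were dendritic and Langerhans cell markers -0.87 (0 of 18 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 0.0019, adjusted p = 0.36 with an estimated correlation), HIF targets -0.58 (0 of 33 higher and 0 lower, 0 and 3 adjusted over the list alone, camera adjusted p = 7.5e-04, adjusted p = 0.16 with an estimated correlation), basal keratinocyte and hemidesmosome genes -0.56 (0 of 18 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 0.019, adjusted p = 0.52 with an estimated correlation) and suprabasal differentiation and cornified envelope -0.39 (0 of 45 higher and 0 lower, 0 and 1 adjusted over the list alone, camera adjusted p = 0.0077, adjusted p = 0.69 with an estimated correlation). Fry passed only the HIF list of these, and 1 or more omissions ended the calls of the adipocyte, dendritic, basal and suprabasal lists. The melanocyte value was raised by wild-type DMSO replicate 2 (mean log2 CPM 4.81, 2.09 in replicate 1).

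The first pattern weighed was the 4752 genes that differed between knockout and Cre-negative skin with DMSO, where all knockout libraries were female and 2 of 3 Cre-negative libraries male. The 10 possible splits of these 6 libraries are too few for a share under 0.05, with 4752 genes for the real split and 0 for the highest other (1 of 10 splits gave as many). If sex were the cause, female minus male within Cre-negative DMSO skin would track the genotype effect, but over 4611 autosomal genes the slope was 0.0492 (0.0339 to 0.0549 with libraries left out), where a slope of 1.5 would be needed, and it was 0.00427 in the imiquimod contrast of Cre-negative males with wild-type females, which shares no library with the comparison. This argues against a sex effect shared by the genotypes as the main source. A sex effect present only in knockout skin, or a cage or batch that goes with sex, stays open, and the slope rests on 1 female library. A difference in skin site stays open as well. The labels do not give the site, and the muscle, adipocyte and trunk HOX lists fell in knockout skin (medians -2.23, -1.36 and -0.79). Induction is given for knockout mice alone, so it cannot be told apart from the genotype. The loss of Nedd8 in keratinocytes may account for the pattern as the design intends.

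The second pattern was the 1776 genes changed by imiquimod in knockout skin, where treatment and sex coincide. Over 1727 autosomal genes, male minus female within Cre-negative DMSO skin had a slope of -0.0657 on the fold change (-0.0708 to -0.0606), where 1 would be needed, and the slopes from wild-type females were 0.0474 and 0.0821. The sex term left 210 genes, with a larger median standard error and a median absolute log2 fold change going from 2.32 to 2.28. The medians of some lists moved further, as given above. Only Cre-negative DMSO skin held both sexes, so the sex term rests on its 1 female and 2 male libraries. It therefore does not show the pattern to be kept. A sex effect on the response of knockout skin alone could still contribute, and no library here separates it from the treatment.

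The third pattern was the higher neutrophil list in imiquimod-treated knockout skin, beside fibroblast and extracellular matrix genes with a smaller shift, of which 7 of 25 rose (9 rose adjusted over the list alone), with a median of 0.85 (camera adjusted p = 0.034, adjusted p = 0.66 with an estimated correlation), a call that ended with fry and without Cre-negative or knockout imiquimod replicate 1. The dendritic and Langerhans cell list went the other way. A lower share of epidermis in these samples would raise the markers of all other cell types alike. The neutrophil median exceeded the fibroblast median by 4.51 (4.41 to 4.93 with libraries left out), so a lower epidermal share alone may explain the smaller fibroblast shift and not the neutrophil shift. More neutrophils, or more transcripts per neutrophil, stay open as biological explanations. So does a site difference, of which the trunk HOX list gave no sign (median -0.06, 3 of 22 rose, camera adjusted p = 0.83).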

How the results depend on the processing

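The sex term, the female libraries and both ribosomal RNA omissions were chosen after seeing the data. All other alternatives were planned. Replicate numbers did not pair the libraries in one way across all groups, as correlations between libraries of the same number ran from -0.32 to 0.49. Between Cre-negative and knockout DMSO skin they were 0.260, 0.102 and 0.166, against -0.268 to 0.104 for other numbers, so a pairing there stays open, and a block for replicate number gave 4692, 2781, 2826, 1263, 3415 and 3623 genes in the 6 main comparisons in the order knockout with DMSO, knockout with imiquimod, imiquimod in Cre-negative, knockout and wild-type skin, and difference between responses. Under the alternatives the values of named genes kept direction and side of the threshold in 25930 cases, lost the call in 1335, gained it in 519 and changed direction in 2. List tests kept theirs in 2581 cases, lost the call in 323 and changed direction in 5.

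Knockout with DMSO gave 7297 genes with voom, 1448 with a sex term, 979 with female libraries only and 3123 to 4294 with 1 library left out. Knockout with imiquimod gave 1790 with voom and 796 to 2360 with 1 library left out. Imiquimod in Cre-negative skin gave 1762 without the libraries high in 18S and 1272 to 2238 with 1 library left out. For imiquimod in knockout skin a model of only the groups compared gave 1028, the sex term 210 and omissions 339 to 1729. For wild-type skin only the groups compared gave 1863 and omissions 1092 to 3531. The difference between responses of knockout and Cre-negative skin gave 1469 with the sex term and 1174 to 3733 with omissions. Omissions left fewer libraries and the sex term went with larger standard errors, and the cause was otherwise not tested.

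Where edgeR called 0 genes, Cre-negative against wild-type skin with DMSO gave 446 without a filter, 144 with DESeq2, 195 with voom, 18 with only the groups compared, 3 with the replicate block, 1 without the libraries high in 18S and 0 to 188 with 1 library left out. With imiquimod these were 763 without a filter, 542 with DESeq2, 18 with only the groups compared, 9 with the block and 0 to 557 with omissions. The difference between their responses gave 203 without a filter, 53 with DESeq2 and 0 to 4 with omissions. The cause was not tested.

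With an estimated correlation 0 lists passed in each of the 9 comparisons. Fry passed 6, 2 and 1 lists in the comparisons of Cre-negative with wild-type skin with DMSO, with imiquimod and between responses, and omissions gave 4 to 8 lists with imiquimod and 7 to 13 between responses. The slope of the knockout response on the Cre-negative response was taken over genes chosen anew under each setting. It was -0.0738 with library size alone, 0.110 with the sex term, and ran from -0.0325 to 0.0609 with 1 library left out. The cause was not tested. Nedd8 with DMSO passed with library size alone (-0.95) and voom (-0.84) but with no other setting. Also chosen anew, genes higher with imiquimod in wild-type skin had medians of 0.96 to 1.81 in knockout DMSO skin, lower ones -1.86 to -1.29.

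Direction changed in a few cases. Without wild-type DMSO replicate 2 the hair shaft list stood at 3.88 for imiquimod in wild-type skin (omissions from -7.74), and for Cre-negative against wild-type skin with DMSO the cell cycle list stood at 0.25 (from -0.79) while the test of the differentiation list turned downward at a median of 0.10 (up to 1.01). With the sex term the interferon list stood at 0.091 and 0.48 for Cre-negative against wild-type skin with DMSO and with imiquimod, and the Y-linked Eif2s3y and Kdm5d at -1.55 and -2.52 for imiquimod in knockout skin. The cause was not tested. DESeq2 gave no adjusted p for S100a8 in any of the 9 comparisons. Depth limited low genes, as 3 counts over a group correspond to 0.0601 to 0.137 CPM.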

Other observations

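Both tests of hypotheses in this part were chosen after their result was seen.

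Of the 42 neddylation and cullin-RING ligase core genes, 7 rose and 1 fell in knockout DMSO skin (6 and 1 adjusted over the list alone), with a median of 0.18 that did not pass (camera adjusted p = 0.13, adjusted p = 0.40 with an estimated correlation). The list passed with fry (adjusted p = 0.034). For imiquimod in knockout skin 1 of 42 fell (1 fell adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.038, adjusted p = 0.28 with an estimated correlation), a call that ended with library size alone, a stricter filter, a sex term and 3 of the omissions. Ube2m (1.41 ± 0.25), the conjugating enzyme of NEDD8, rose by edgeR's test, and its call ended with the sex term and with female libraries only. Of the 18 SUMO machinery genes 3 rose and 3 fell (3 and 3 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.51, adjusted p = 0.65 with an estimated correlation). Mast cell and basophil genes did not pass as a list in knockout DMSO skin (median 0.32, 2 of 10 rose, 2 adjusted over the list alone, camera adjusted p = 0.12, adjusted p = 0.56 with an estimated correlation), while Hdc (3.67 ± 0.37), the histamine-forming enzyme that neutrophils and basophils also express, rose.

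Hair-cycle genes differed between replicates of wild-type skin. The mean log2 CPM of the hair shaft and inner root sheath list was 0.34 and 7.16 in wild-type DMSO replicates 1 and 2 and 3.93 and -0.21 in wild-type imiquimod replicates 1 and 2. The cartilage list stood at 3.26 in wild-type DMSO replicate 2 and at 0.88 in replicate 1. The mean of the HOX genes of trunk position lay between 2.68 and 3.17 in the wild-type and Cre-negative DMSO libraries. In the imiquimod and knockout libraries it lay lower, between 1.41 and 2.11.

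The absence of Il17a reads in imiquimod-treated knockout skin was set against a loss of T cells. At the level of Cre-negative imiquimod skin 39.7 reads of Il17a were expected in the 2 knockout imiquimod libraries, at the level of wild-type imiquimod skin 6.31, and 0 were observed, with 1 read in knockout DMSO skin. A candidate explanation is that fewer T cells were present. The median fold change of the T cell and NK cell list was -1.26 (-1.37 to -0.51 with libraries left out), in the direction of that explanation, and the list did not pass (camera adjusted p = 0.098, adjusted p = 0.39 with an estimated correlation). Its members went both ways, with 2 higher and 3 lower (2 and 3 adjusted over the list alone), among them Icos (-3.49), so the test leaves this open.

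The rise of NRF2 targets in knockout skin was set against the inflammation that imiquimod also gives. If inflammation alone raised them, knockout skin with DMSO and wild-type skin with imiquimod would raise them alike. Over the 37 genes the knockout fold change exceeded the imiquimod fold change in wild-type skin by a median of 2.55 (1.83 to 2.69 with libraries left out), with 11 genes past the threshold of the difference itself (25 adjusted over the list alone) and 0 in the other direction, camera p = 1.1e-20 and p = 0.0012 with an estimated correlation. This argues against that inflammation as the sole source, and one hypothesis is that NRF2, a substrate of a cullin 3 ligase, may be stabilised when NEDD8 is lost, which protein measurements would have to test.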
